A study of Mus musculus with 6 samples.

How the data were processed

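The data are RNA-seq profiles of whole mouse kidney, with 3 libraries per group. Groups and replicate numbers were taken from the sample titles, and the doses and times from the series' design text. The design text gives 6 animals per group, of which 3 libraries per group were analysed here, and the labels place all libraries in a single batch. The labels do not say outright that each library is a separate animal, so p-values measure the spread between these libraries. The design text describes the ischemia in different words for the 2 groups (partial bilateral ischemia with saline, occlusion of both renal arteries with tacrolimus), and whether the surgery differed is not known. The series title names zafirlukast, but the labels of these libraries name tacrolimus, and they are treated as such.

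RNA was extracted with TRIzol or with a column kit and DNase, per the labels' protocols, and libraries followed standard Illumina methods. The design text speaks instead of the supernatant of a homogenate in buffered saline. Which kit was used for which library, whether the library kit marks strand, and the aligner, counter and annotation release are not given in the sources used here. The genome build is GRCm39, per the submitters' processing notes. Coordinates and gene names are those of the deposited table, since the mouse reference at hand was of another build and was not used.

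The deposited table has 56747 gene rows, each with a raw read count and an FPKM value per library, per the file headers. The deposited counts are whole numbers, not normalized. The deposited FPKM values divide each count by a gene length and by a library total. The total implied by the values is 0.950 to 1.03 times the count sum of the library, so a scaling between libraries is already in them. The table gives each gene's start, end and length, and 1 row is not analysed here. No column of another sample was present. A gene that overlaps another model, or shares exons with it, has a count that depends on how the authors assigned shared reads. Strand use is not given, so antisense partners cannot be told apart either.

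Before the data were examined, the tests, the gene lists, the rule for naming genes and the alternatives were fixed, with the count test as the main test if counts were found. Counts were analysed with edgeR 4.0.16 in R 4.3.3. Genes were kept by filterByExpr (minimum count 10, minimum total 15), which left 17557. TMM factors scaled the libraries (0.942 to 1.03), and glmQLFit with robust moderation and glmQLFTest gave two-sided p-values, adjusted by Benjamini-Hochberg over all genes tested. The threshold was an adjusted p of 0.05, and for the count of larger changes also a fold of at least 2. The SE of a log2 fold change was taken from the fold change and its F statistic. The biological coefficient of variation was 0.304. CPM values are counts divided by the TMM-scaled library size, times 1e6. With at least 38443534 counts in a library, 1 CPM stands for some 38.4 counts or more, so for the genes named the spread between libraries, not counting, sets the error, except for genes under 1 CPM. Replicates were checked for duplicates with a chi-square per degree of freedom of the counts of each pair, and none agreed within sampling noise. Principal components and distances used log2 CPM with a prior count of 2.

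The 43 gene lists cover nephron segments, tubular injury, vessels, matrix, immune cells, other tissues, and pathways of inflammation, stress, cell death, metabolism and calcineurin. The 40 lists with at least 5 tested members were tested with camera (limma 3.58.1) at a preset inter-gene correlation of 0.01, adjusted over these lists, and again with an estimated correlation and with fry. Some genes stand in more than 1 list. Named genes are, per direction, up to 10 called genes with the largest fold, no overlap between groups, at least 1 CPM in the higher group and a symbol that is not a predicted model. Where fewer than 5 qualified, the list was filled to 5 with the smallest unadjusted p. To these come up to 4 members of each list with the smallest unadjusted p, and 11 genes fixed by name. A selection of them is described in the text, and 1 gene is not reported here. Genes outside the rule are said to be so where they appear.

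The test was tried on simulated counts drawn from the real means, dispersions and library sizes of this comparison, over 17557 genes with 200 changed. Of 50 genes each, edgeR recovered 4 at 2-fold, 24 at 4-fold, 41 at 8-fold and 44 at 16-fold, and called 6 unchanged genes. DESeq2 1.42.0 recovered 19, 37, 45 and 47, and called 63 unchanged genes. A list shifted 2-fold had an adjusted p of 4.61e-17 with the preset correlation and 0.0287 with an estimated one. Of 39 unchanged lists 2 were called with the preset correlation and 0 with an estimated one. The simulated genes were drawn independently, whereas real lists had estimated correlations such as 0.509 (tubular injury) and 0.767 (immediate early). The simulation therefore cannot show how often the list test calls unchanged lists whose genes vary together.

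The alternatives were DESeq2, limma-trend on log2(FPKM + 1) of genes with an FPKM of at least 1 in 3 libraries, a pseudocount of 0.1, no filter and a mean FPKM of at least 5, quantile and TMM-type scaling of FPKM, moderation without trend, library weights, the replicate number as a block, and each library left out in turn. Added after seeing the data were RLE scaling, no scaling, leaving out mitochondrial genes, moderation that is not robust, and the list test with an estimated correlation without saline replicate 1. Pathways in the observations come from the annotation in the deposited table, without those numbered as human disease pathways. Some named after a disease or drug resistance remained under other numbers, such as type II diabetes mellitus and platinum drug resistance. Plots were drawn with matplotlib 3.10.9 in Python 3.11.15.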

Results

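Whole-kidney RNA of male C57BL/6J mice, an inbred laboratory strain, was profiled after ischemia-reperfusion, an injury made by stopping and then restoring the renal blood supply. The clamp lasted 30 min and reperfusion 24 h. The 6 libraries fall into 2 groups of 3. In the saline group the mice had received oral saline, and in the tacrolimus group 1 mg/kg/day of oral tacrolimus for 1 day. The design text words the ischemia differently for these groups, as given above, so a difference in surgery could not be told apart from treatment. Tacrolimus is an immunosuppressant that binds FKBP12, the product of Fkbp1a, and so inhibits the phosphatase calcineurin. No uninjured kidney is among the 6 libraries, so each value compares injured kidneys with injured kidneys. Gene-level totals were 40275367, 38443534 and 44476844 counts in saline replicates 1 to 3 and 43568361, 41011827 and 42024284 in tacrolimus replicates 1 to 3. Between 22512 and 22809 genes had at least 1 count. Levels below are CPM values after TMM scaling, given as mean ± SD with n = 3 per group, and folds compare tacrolimus with saline.

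The comparison asks which kidney transcripts differ with tacrolimus at 24 h of reperfusion. Kidneys from tacrolimus-treated mice held less of the transcripts of injured tubules and more of those of the proximal tubule. Havcr1, which encodes the injury marker KIM-1, stood at 63.7 ± 52.0 CPM against 982 ± 671 CPM in saline (SD, n = 3 each). All 32 tested members of the tubular injury list had the lower value with tacrolimus, and 32 of 35 proximal tubule genes the higher value. Camera called both lists with a preset correlation and neither with an estimated one (adjusted p = 0.446 for each with an estimated correlation). At the level of single genes only Ugt1a9 and Gsk3b passed the test, and both fell. The size of the injury difference came mostly from saline replicates 2 and 3, since saline replicate 1 lay close to the tacrolimus libraries.

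Ugt1a9, a glucuronosyltransferase of the drug-conjugating Ugt1a cluster, was almost lost with tacrolimus. It had 0.386 ± 0.134 CPM with tacrolimus and 68.5 ± 16.3 CPM with saline, a log2 fold change of -7.46 ± 0.32 (SE; adjusted p = 0.00217, edgeR quasi-likelihood test). The counts behind it were 23, 13 and 13 with tacrolimus and 3596, 2234 and 2579 with saline. The gene (ENSMUSG00000090175) spans 87998522 to 88146719 on chromosome 1 of GRCm39. It overlaps the other Ugt1a models, which are known to share exons, so its count is uncertain where the counting could split shared reads. Gsk3b, which encodes glycogen synthase kinase 3 beta, fell to 30.2 ± 2.27 CPM from 85.0 ± 1.00 CPM, a log2 fold change of -1.49 ± 0.11 (SE; adjusted p = 0.0306, edgeR). It is ENSMUSG00000022812, at 37909363 to 38066446 on chromosome 16. Both genes separated all 3 tacrolimus libraries from all 3 saline libraries, saline replicate 1 included.

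**Figure D1:**
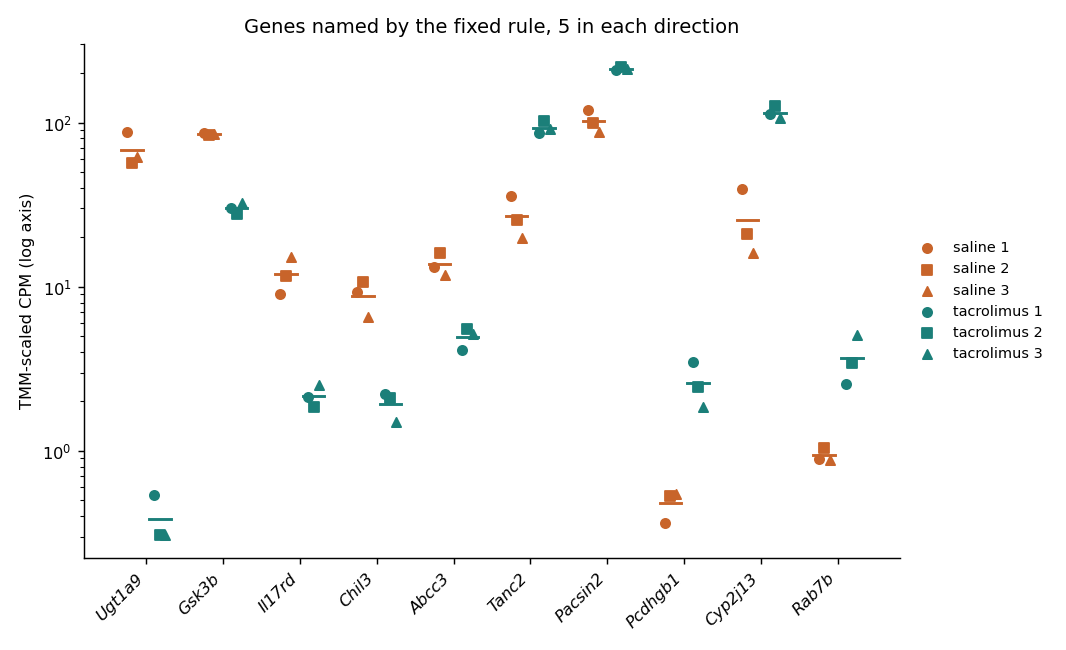
TMM-scaled CPM on a log axis for the 5 genes per direction named by the fixed rule, with 1 point per library and a horizontal line at each group mean. Ugt1a9 lies at 0.308 to 0.541 CPM in the tacrolimus libraries and at 56.8 to 87.1 CPM in the saline libraries.

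The next genes in order of p, none of which passed the test (adjusted p from 0.222 to 0.392, edgeR), kept the groups apart in all 6 libraries, as the naming rule requires. On the lower side, Il17rd, a membrane regulator of growth factor signaling, was at 2.17 ± 0.343 CPM with tacrolimus and 12.0 ± 3.08 CPM with saline. Chil3, a chitinase-like protein of activated macrophages, was at 1.94 ± 0.389 and 8.80 ± 2.10 CPM. Abcc3, an organic anion exporter, was at 4.93 ± 0.739 and 13.7 ± 2.19 CPM. On the higher side, the scaffold gene Tanc2 had a fitted fold of 3.46 and the endocytic adaptor gene Pacsin2 a fold of 2.08. Cyp2j13, a cytochrome P450, was at 115 ± 10.4 CPM with tacrolimus and 25.4 ± 12.2 CPM with saline. Pcdhgb1 and Rab7b, both under 4 CPM on average, had folds of 5.36 and 3.91. The models of the protocadherin cluster overlap, so the Pcdhgb1 count is uncertain in the same way as that of Ugt1a9.

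In all, 17557 genes were tested, of which 2 had an adjusted p under 0.05, both lower and both by at least 2-fold. Of these, 3826 genes (21.8%) kept the groups apart without overlap. The average over all equal splits of the libraries is 10%, but genes vary together, so a single split can exceed it without a treatment effect. The share was not computed for the other splits, so no group difference is concluded from it. At an unadjusted p under 0.05 there were 2223 genes, 868 higher and 1355 lower. Without saline replicate 1 the same test called 2534 of 18081 genes, 1420 higher and 1114 lower, among them both genes named above, and DESeq2 on all 6 libraries called 344. Without any of the other 5 libraries in turn it called 0 or 1 gene: Gsk3b lost its call each time, and Ugt1a9 without tacrolimus replicate 2 (adjusted p = 0.0564, edgeR). The log2 fold change of Gsk3b stayed between -1.55 and -1.24 under every alternative, so its size held where its call was lost. Saline replicate 1 is the saline library nearest to the tacrolimus libraries, so leaving it out favors larger group differences. List members called without it, counted below, are to be read against the 2534 of 18081 genes called then.

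**Figure D2:**
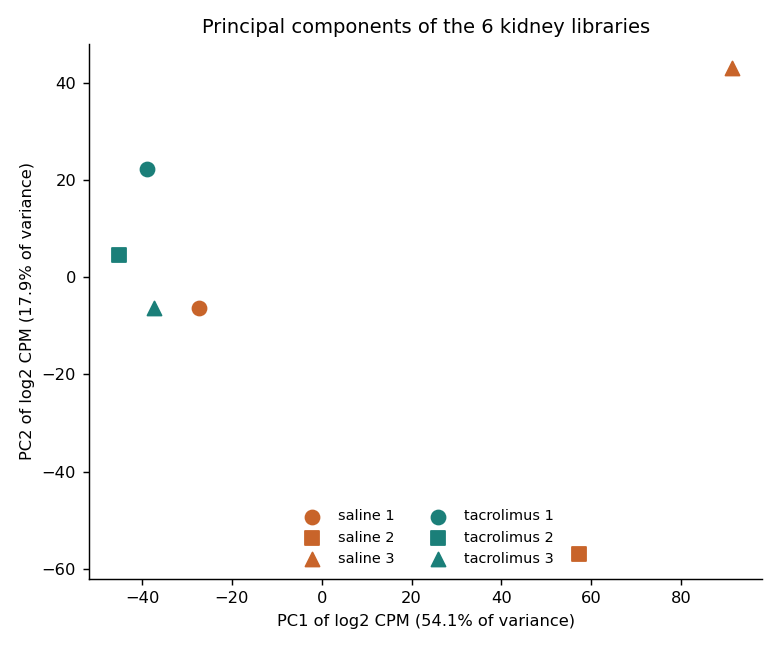
First 2 principal components of log2 CPM, each axis with its share of the variance, with 1 point per library, colored by group. Saline replicate 1 has a PC1 score of -27.3, next to the tacrolimus libraries at -37.5 to -45.1, while saline replicates 2 and 3 lie at 57.4 and 91.3.

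The libraries did not separate by treatment alone. PC1 held 54.1% of the variance, and on it saline replicate 1 stood beside the tacrolimus libraries. Across the tested genes its root-mean-square log2 difference was 0.592 to 0.612 from the tacrolimus libraries, against 0.867 from saline replicate 2 and 1.04 from saline replicate 3. The tacrolimus libraries differed from each other by 0.576 to 0.613. The share of counts from the mitochondrial genome was 16.5 ± 0.525% with tacrolimus and 17.8 ± 1.24% with saline.

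The tubular injury and repair list was the one with the smallest p. All 32 tested members were lower with tacrolimus, with a median log2 fold change of -1.65. By the edgeR test 0 of them passed over all genes tested and 23 passed adjusted over the list alone. Krt20, a keratin of injured tubule cells, was at 5.0 ± 2.61 CPM with tacrolimus and 287 ± 315 CPM with saline. Lcn2, which encodes the iron-binding protein NGAL, was at 50.3 ± 20.5 and 1065 ± 1348 CPM. The small proline-rich protein gene Sprr1a was at 15.1 ± 4.87 and 44.9 ± 13.4 CPM, and Cp, which encodes ceruloplasmin, at 120 ± 13.7 and 231 ± 63.2 CPM. In saline replicate 1 Havcr1 stood at 268 CPM, Lcn2 at 77.1 and Krt20 at 13.4. All of these values are above those of every tacrolimus library (at most 118, 72.2 and 7.96 CPM) and far below those of saline replicates 2 and 3 (at least 1081, 517 and 216 CPM). Havcr1 lies at 46625907 to 46670405 and Krt20 at 99319229 to 99328976 on chromosome 11, and Lcn2 at 32274645 to 32278264 on chromosome 2. The list was called lower by camera with a preset correlation of 0.01 (adjusted p = 3.98e-22), but not with an estimated one (adjusted p = 0.446 with an estimated correlation). Without saline replicate 1, 22 of the 32 members were called over all genes tested.

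**Figure D3:**
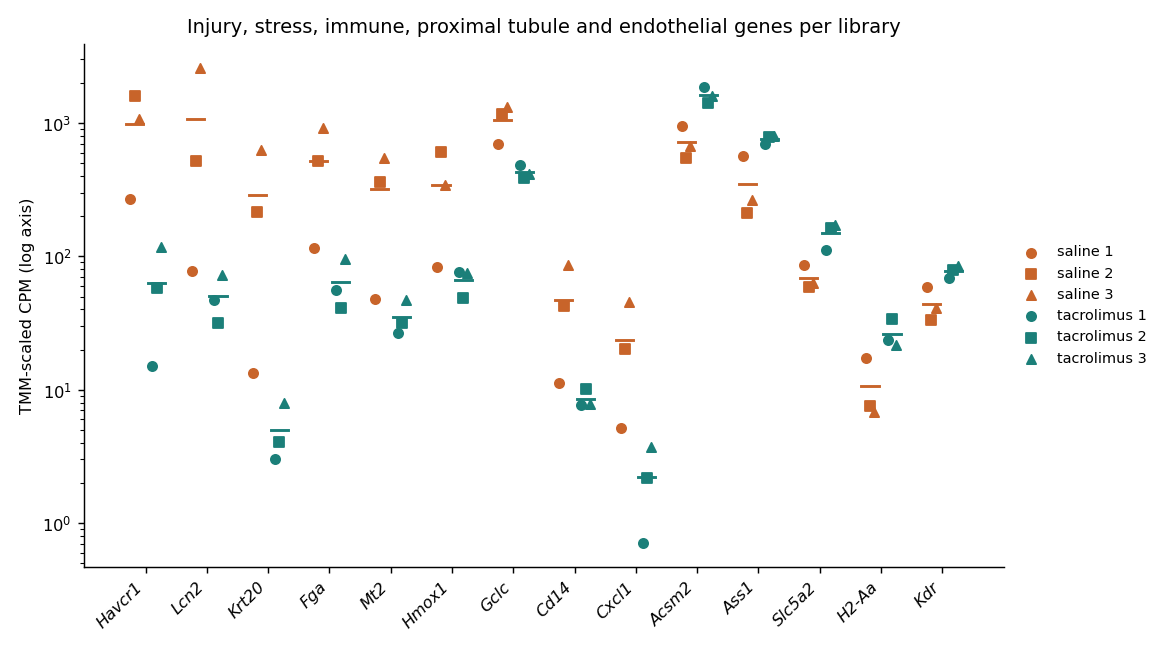
TMM-scaled CPM on a log axis for genes of tubular injury, stress, inflammation, proximal tubule, antigen presentation and endothelium, with 1 point per library and a line at each group mean. For Havcr1, Lcn2 and Krt20 saline replicate 1 lies between the tacrolimus libraries and saline replicates 2 and 3.

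Genes of the proximal tubule, the segment that reabsorbs most of the filtrate, went the other way. Of 35 tested members 32 were higher with tacrolimus, with a median log2 fold change of 0.83. Over all genes tested 0 passed, and 2 passed adjusted over the list alone, Acsm2 and Slc5a2. Acsm2, a medium-chain acyl-CoA synthetase, was at 1632 ± 225 CPM with tacrolimus and 722 ± 201 CPM with saline. Slc5a2, the glucose transporter SGLT2, was at 150 ± 32.4 and 69.4 ± 14.3 CPM. Ass1, argininosuccinate synthase of the arginine pathway, was at 756 ± 55.0 and 348 ± 189 CPM, and the organic anion transporter Slco1a1 at 69.8 ± 34.9 and 25.2 ± 11.8 CPM. Camera called the list higher (adjusted p = 2.28e-11; adjusted p = 0.446 with an estimated correlation). The median member of the list lay 0.32 above its 6-library mean (log2) in saline replicate 1, 0.44 to 0.51 above it with tacrolimus, and 0.75 and 0.88 below it in saline replicates 2 and 3. Without saline replicate 1, 18 of 35 members were called higher over all genes tested (adjusted p = 0.0726 for the list with an estimated correlation).

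Other tubule segments and the vessels showed the same direction. All 14 thick ascending limb genes were higher (median log2 fold change 0.87), among them the potassium channel gene Kcnj1 at 304 ± 22.9 CPM against 163 ± 97.7 CPM. Of the intercalated cell genes 12 of 14 were higher. Of the endothelial genes 14 of 15 were higher, with Kdr, the VEGF receptor 2, at 77.7 ± 7.63 against 44.3 ± 12.9 CPM and Ehd3 at 55.0 ± 6.92 against 29.8 ± 10.4 CPM. The fibroblast, pericyte and matrix list was higher in 18 of 23 members, with Pdgfrb, a receptor of pericytes, at 62.3 ± 7.44 against 46.2 ± 3.89 CPM. With all 6 libraries 0 members of these lists passed over all genes tested or adjusted over the list alone. When saline replicate 1 was left out, 8 of 14, 6 of 14, 9 of 15 and 7 of 23 were called higher in the order above, and 1 of the last list lower. Camera called all 4 lists higher, with adjusted p = 4.23e-05 for the thick ascending limb, 0.000796 for intercalated cells, 3.44e-05 for endothelium and 0.00141 for fibroblasts. With an estimated correlation the adjusted p was 0.482, 0.474, 0.450 and 0.482 in the same order. Saline replicate 1 again had list medians above the 6-library mean (by 0.40, 0.09, 0.13 and 0.12), as the tacrolimus libraries did, while saline replicates 2 and 3 lay below it.

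The neutrophil list was lower with tacrolimus in all 14 tested members (median log2 fold change -2.20), and its members Mmp9, Cxcr2 and S100a8 were scarce in every library. The gelatinase gene Mmp9 stood at 0.449 ± 0.0689 CPM against 2.13 ± 0.933 CPM, and the chemokine receptor Cxcr2 at 0.252 ± 0.0277 against 1.44 ± 0.807 CPM. S100a8, a calprotectin subunit, was at 0.953 ± 0.0845 against 5.10 ± 3.92 CPM. More abundant was Lrg1, a secreted acute-phase glycoprotein, at 10.9 ± 2.93 against 87.5 ± 71.8 CPM. Of the 14 members 0 passed over all genes tested and 10 passed adjusted over the list alone, and without saline replicate 1, 9 of 16 were called over all genes tested. Camera called the list lower (adjusted p = 5.48e-13; adjusted p = 0.412 with an estimated correlation). In saline replicate 1, 11 of the 14 members were above all 3 tacrolimus libraries and 9 were also below both other saline libraries.

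The lists of cytokines, NF-kB targets and immediate early genes were mostly lower too. Cytokines and chemokines were lower in 19 of 28 tested members, and 6 passed adjusted over the list alone. The neutrophil-attracting chemokines Cxcl2 (0.465 ± 0.130 against 3.22 ± 1.46 CPM) and Cxcl1 (2.21 ± 1.52 against 23.6 ± 20.3 CPM) were among those with the smallest p. Cxcl10 was at 3.85 ± 1.02 against 9.57 ± 3.34 CPM, and the interleukin-6 family cytokine Lif at 1.86 ± 1.12 against 13.4 ± 8.55 CPM. NF-kB targets were lower in 15 of 21 members, and 8 passed adjusted over the list alone. They include Birc3, an inhibitor of apoptosis, at 9.17 ± 1.63 against 21.5 ± 5.27 CPM. The NF-kB subunit genes Nfkb2 and Relb were at 18.6 ± 2.66 against 36.4 ± 8.93 and 5.39 ± 0.597 against 12.6 ± 4.4 CPM. Immediate early genes were lower in 23 of 24 members, 13 of them adjusted over the list alone, with Junb at 15.5 ± 3.95 against 59.6 ± 36.5 CPM and Fosl2 at 21.8 ± 1.04 against 51.9 ± 22.6 CPM. Over all genes tested 0 members of these 3 lists passed, and without saline replicate 1 there were 6 of 32, 7 of 22 and 16 of 25 called lower and 3 NF-kB targets called higher. Camera called them lower, with adjusted p = 0.000141 for cytokines, 0.000141 for NF-kB targets and 2.28e-11 for immediate early genes (adjusted p = 0.446, 0.412 and 0.446 with an estimated correlation). The cytokine list lost its call without tacrolimus replicate 1 (adjusted p = 0.0646). Each of the 9 genes named here was higher in saline replicate 1 than in every tacrolimus library and lower than in both other saline libraries. They were named for a small p with saline replicate 1 counted as saline, which favors values above the tacrolimus libraries. Over all tested members the same position was held by 6 of 28 cytokines, 7 of 21 NF-kB targets and 12 of 24 immediate early genes. The cytokine list median, as log2 from the 6-library mean, was 0.18, 0.94 and 0.01 in saline replicates 1 to 3 and -0.77, -0.44 and 0.09 in tacrolimus replicates 1 to 3. The NF-kB median was 0.16, 0.30 and 0.14 in the saline libraries and -0.27 to -0.16 with tacrolimus. The immediate early median was -0.35, 0.70 and 1.43 in the saline libraries and -0.83 to -0.41 with tacrolimus.

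Stress and cell death lists followed. NRF2 antioxidant genes were lower in 17 of 23 members, 9 of them adjusted over the list alone. Gclc, the catalytic subunit of the enzyme that limits glutathione synthesis, was at 428 ± 52.2 against 1059 ± 322 CPM. The metallothionein gene Mt2 was at 35.0 ± 10.4 against 318 ± 251 CPM, and the cystine transporter gene Slc7a11 at 0.465 ± 0.0724 against 3.91 ± 2.71 CPM. Ferroptosis genes were lower in 14 of 19 members, 6 of them adjusted over the list alone. These include Fth1, the ferritin heavy chain, at 3631 ± 222 against 8143 ± 2461 CPM, and Hmox1, heme oxygenase 1, at 66.8 ± 15.8 against 346 ± 263 CPM. Slc7a11, Fth1 and Hmox1 are known to act against ferroptosis or to be induced by oxidative stress. Pyroptosis and necroptosis genes were lower in 16 of 22 members, 0 of them adjusted over the list alone. No member of the 3 lists passed over all genes tested, and without saline replicate 1 there were 11 of 23, 8 of 19 and 5 of 22 called lower and 1 NRF2 gene called higher. Camera called the 3 lists lower (adjusted p = 4.23e-05, 0.000379 and 0.0105; adjusted p = 0.446 for each with an estimated correlation). Saline replicate 1 had list medians of -0.10, -0.05 and -0.07 (log2 from the 6-library mean), and saline replicates 2 and 3 had medians of at least 0.22.

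**Figure D4:**
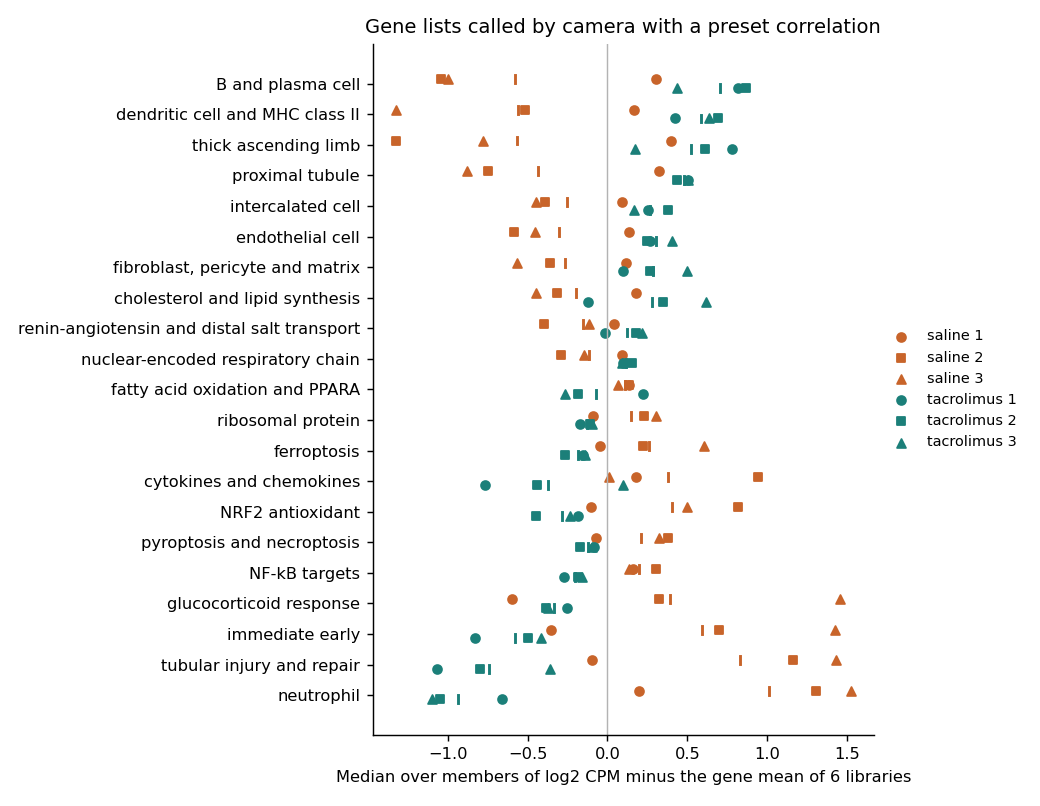
For each of the 21 lists called by camera with the preset correlation, the median over members of log2 CPM minus the gene's mean over the 6 libraries, with 1 point per library and a short vertical line at each group mean. In the tubular injury list saline replicate 1 lies at -0.10, the tacrolimus libraries at -1.07 to -0.36 and the other saline libraries at 1.16 and 1.43.

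Of the immune cell lists only that of neutrophils was called lower. All 11 tested dendritic cell and MHC class II genes were higher with tacrolimus, with H2-Aa at 26.4 ± 6.71 against 10.6 ± 5.93 CPM and H2-Ab1 at 25.6 ± 3.94 against 12.9 ± 5.90 CPM. No member passed over all genes tested or adjusted over the list alone (camera adjusted p = 3.29e-06; 0.446 with an estimated correlation). Of 6 tested B and plasma cell genes 5 were higher, 0 of them adjusted over the list alone (camera adjusted p = 0.00701; 0.446 with an estimated correlation). Without saline replicate 1, 5 of 11 and 3 of 7 members were called higher over all genes tested. Saline replicate 1 had list medians of 0.17 and 0.31, on the side of the tacrolimus libraries. Macrophage and monocyte genes went both ways, 17 higher and 12 lower of 29, and the list was not called (camera adjusted p = 0.237). Chil3, given above, was its 1 member that passed adjusted over the list alone, and 6 members were called higher and 3 lower over all genes tested when saline replicate 1 was left out. Cd14 and Cd68, a lipopolysaccharide co-receptor and a lysosomal protein, were at 8.49 ± 1.34 against 46.8 ± 37.8 CPM and 9.54 ± 2.44 against 22.5 ± 11.5 CPM. The resident macrophage marker Adgre1, which encodes F4/80, was at 5.66 ± 1.27 against 2.11 ± 2.39 CPM. For Adgre1, saline replicate 1 at 4.82 CPM lay within the range of the tacrolimus libraries, and saline replicates 2 and 3 stood at 1.22 and 0.287 CPM.

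With all 6 libraries the transcripts of the drug's target pathway showed no difference that passed the test. RNA levels do not measure the activity of calcineurin, so whether the drug inhibited it cannot be told from them. Of 23 calcineurin, NFAT and FK506-binding protein genes 12 were higher and 11 lower, 0 of them adjusted over the list alone (camera adjusted p = 0.874). The median and the test point up and the mean down, all near 0. Fkbp1a was at 74.8 ± 36.3 CPM with tacrolimus and 79.8 ± 27.6 CPM with saline (adjusted p = 0.915, edgeR), and its direction turned when tacrolimus replicate 1 or saline replicate 3 was left out. The calcineurin catalytic subunit genes Ppp3ca and Ppp3cb had log2 fold changes of -0.14 ± 0.15 and 0.33 ± 0.17 (SE), and Nfatc1 -0.29 ± 0.21. Rcan1, a calcineurin inhibitor that NFAT induces, was at 108 ± 21.3 against 170 ± 51.3 CPM, with overlapping groups (adjusted p = 0.393, edgeR). Fkbp5, also a target of the glucocorticoid receptor, was at 109 ± 13.2 against 219 ± 150 CPM, with overlapping groups. Of the 23 members 2 were called lower without saline replicate 1, Rcan1 (log2 fold change -0.88) and Fkbp5 (-1.44).

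The series title names zafirlukast, a cysteinyl leukotriene receptor blocker, and extracellular traps released by macrophages, so both gene groups were measured. Of 21 leukotriene and arachidonic acid genes 11 were higher and 10 lower (camera adjusted p = 0.0848), and 6 of 22 were called higher over all genes tested without saline replicate 1. The receptor gene Cysltr1 was at 0.836 ± 0.207 CPM with tacrolimus and 0.561 ± 0.160 CPM with saline (adjusted p = 0.482, edgeR). The members with the smallest p encode brush-border enzymes and a receptor of kidney tubules. Dpep1 stood at 59.8 ± 3.38 against 23.2 ± 12.7 CPM, Ggt1 at 561 ± 21.1 against 373 ± 74.4 CPM, and Oxgr1 at 33.1 ± 2.63 against 18.8 ± 7.24 CPM. Of 24 extracellular trap genes 15 were higher and 9 lower (camera adjusted p = 0.669), and 1 passed adjusted over the list alone, Mmp9, which is lower and also in the neutrophil list. With saline replicate 1 left out, 1 trap gene was called higher and 2 lower over all genes tested. The tissue factor gene F3 was at 26.8 ± 1.17 against 54.2 ± 24.6 CPM. Padi4, the histone-citrullinating enzyme of trap formation, was below the count filter, with 2, 0 and 0 counts with tacrolimus and 6, 14 and 8 with saline.

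Lists of metabolism and translation that camera called were ribosomal protein (29 of 30 lower, median log2 fold change -0.28, adjusted p = 4.23e-05), glucocorticoid response (15 of 17 lower, adjusted p = 0.000141) and fatty acid oxidation (22 of 29 lower, adjusted p = 0.0492). Cholesterol and lipid synthesis was higher in all 24 members (adjusted p = 0.000141), the nuclear-encoded respiratory chain in 23 of 28 (adjusted p = 0.00368), and renin-angiotensin and distal salt transport in 14 of 21 (adjusted p = 0.0296). With an estimated correlation these 6 lists had an adjusted p of 0.446 to 0.637. Of their members 4 glucocorticoid response genes passed adjusted over the list alone, and 0 in the other 5 lists. Leaving out saline replicate 1 raised the members called over all genes tested from 0 to 10 ribosomal protein and 8 glucocorticoid response genes, all lower, and to 9 respiratory chain and 5 cholesterol genes, all higher. In fatty acid oxidation 2 were then higher and 3 lower, and in distal salt transport 5 and 2. The 4 are Mt1, Mt2, Cdkn1a and Lcn2, all also known as injury or stress genes. In saline replicate 1 the glucocorticoid list median was -0.60, lower than in any tacrolimus library, and the ribosomal protein (-0.09) and respiratory chain (0.09) medians had the sign of all 3 tacrolimus libraries. The cholesterol median was 0.18 in saline replicate 1 and -0.12, 0.34 and 0.61 in tacrolimus replicates 1 to 3. For fatty acid oxidation it was 0.23 in tacrolimus replicate 1, above the 3 saline libraries (0.06 to 0.13), and -0.18 and -0.27 in tacrolimus replicates 2 and 3. Fatty acid oxidation lost its call without saline replicate 1 (adjusted p = 0.102), tacrolimus replicate 2 (0.219) or tacrolimus replicate 3 (0.381), and distal salt transport without saline replicate 1 (0.0523) or saline replicate 2 (0.151). The respiratory chain lost it without saline replicate 2 (0.0893) and glucocorticoid response without saline replicate 3 (0.137). In all, 21 of 40 tested lists were called with the preset correlation, 10 higher and 11 lower. With an estimated correlation 0 were called and 3 had an unadjusted p under 0.05, and fry called 0, with 7 at an unadjusted p under 0.05.

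The remaining lists were not called by camera. Complement and coagulation (adjusted p = 0.760) had a median above 0 and a mean below 0. Its fibrinogen genes Fga and Fgg were at 64.2 ± 28.2 against 520 ± 405 CPM and 46.9 ± 31.8 against 400 ± 307 CPM, and both are among 5 lower and 1 higher that passed adjusted over the list alone. Over all genes tested, 7 of its members were called lower and 3 higher without saline replicate 1. Adipose tissue genes (adjusted p = 0.202) were 4 higher and 4 lower, with 2 lower adjusted over the list alone, the lipid droplet genes Plin1 and Cidec. The adjusted p was 0.105 for interferon response (23 of 34 higher), 0.105 for cell cycle (20 of 30 lower), 0.118 for heat shock, 0.221 for glycolysis and hypoxia, 0.237 for the mitochondrial genome, 0.245 for the circadian clock and 0.874 for endoplasmic reticulum stress, whose median and mean differ in sign. For nephron and glomerular cells it was 0.0848 for collecting duct principal cells, 0.170 for the distal convoluted tubule and 0.196 for podocytes. For cells and tissues that a kidney piece can carry along, it was 0.0633 for red blood cells, 0.149 for T and NK cells and 0.371 for liver. The lower direction of the cell cycle list depended on saline replicate 1. Without it 15 members were higher and 15 lower (median log2 fold change 0.02, camera adjusted p = 0.715 with the preset correlation). Of the skeletal muscle, adrenal gland and pancreas lists 3, 3 and 1 members had enough counts, too few for a test.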

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

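Of the 61 genes followed under 23 alternatives, 1298 pairs of a gene and a setting gave a value: 1147 stayed on their side of the threshold with their direction, 139 passed it newly, 10 lost the call and 2 reversed. Only Ugt1a9 and Gsk3b had a call to lose, so for the other genes staying means staying uncalled. The new passes came without saline replicate 1 (53), in DESeq2 (40) and in limma with library weights (46). Both reversals are Fkbp1a, with a log2 fold change of 0.18 without tacrolimus replicate 1 and 0.19 without saline replicate 3, in a range of -0.55 to 0.19 over the left-out libraries. The count of 2 genes, and of 2 genes changed at least 2-fold, stayed at 2 with no filter or a stricter one in edgeR, with RLE or no scaling, without mitochondrial genes, without robust moderation, and in limma-trend with either pseudocount, either scaling or plain moderation. DESeq2 called 344 genes (266 at least 2-fold), and in simulated data it also called more unchanged genes than edgeR. Limma with library weights, which gave saline replicates 1, 2 and 3 weights of 0.214, 4.75 and 0.232 and so drew its saline level mostly from replicate 2, called 5475 (760 at least 2-fold). Limma-trend without a filter called 1 (1 at least 2-fold), and at a mean FPKM of at least 5 also 1 (1). That filter left 12 lists in limma-trend, which called 19 with its own filter, and 17 in edgeR, which called 21. The cause of these shifts was not tested. Leaving out 1 library at a time gave 0 to 2534 genes and 0 to 1400 genes changed at least 2-fold, with the highest values without saline replicate 1 and 0 without tacrolimus replicate 2; the lists called ranged from 19 to 25, and 16 of the 21 lists kept their call each time. Across all alternatives the adjusted p of Gsk3b reached 0.376 and that of Ugt1a9 0.0564, while their log2 fold changes stayed at -1.55 to -1.24 and -7.78 to -4.56. The list count fell to 0 with an estimated correlation, to 0 with fry, and to 0 with an estimated correlation and without saline replicate 1. DESeq2 gave no list value. No scaling moved the median log2 fold change of all genes by 0.1.

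With the replicate number as a block, edgeR called 1 gene (1 at least 2-fold) and limma-trend called 1 (1), Ugt1a9 in each, while 22 and 21 lists were called. No pairing by number was seen: same-numbered libraries had deviations from their group means that correlated at -0.02, -0.01 and -0.05 across genes. Differently numbered ones correlated at -0.13 to 0.14. So few libraries cannot exclude a shared litter or day. Depth limits statements on genes below about 1 CPM, such as Padi4 and Cysltr1. For more abundant genes the limit is the spread between libraries. Across the tested genes the root-mean-square log2 difference was 0.817 to 1.04 between saline libraries and 0.576 to 0.613 between tacrolimus libraries. Krt20 had the larger SD with saline (315 against 2.61 CPM). Slco1a1 had the larger SD with tacrolimus (34.9 against 11.8 CPM), where its mean was also higher (69.8 against 25.2 CPM).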

Other observations

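Pathways annotated in the deposited table, tested after the lists above, describe further groups. Of 217 pathways with 15 to 300 tested genes, camera with the preset correlation called 39, 20 higher and 19 lower with tacrolimus, and 0 with an estimated correlation (adjusted p of at least 0.673). Among the lower pathways were ribosome biogenesis in 68 of 80 genes (median log2 fold change -0.26, adjusted p = 1.84e-05), the spliceosome in 158 of 198 (-0.21, adjusted p = 9.86e-05), the proteasome in 49 of 55 (-0.22, adjusted p = 0.00113) and base excision repair in 49 of 57 (-0.36, adjusted p = 3.37e-05). The IL-17 signaling pathway had the smallest p, with 63 of 80 genes lower (adjusted p = 4.01e-07). Among the higher pathways were tryptophan metabolism in 25 of 35 genes (0.65, adjusted p = 0.000142), glycine, serine and threonine metabolism in 33 of 41 (0.49, adjusted p = 0.000295) and glyoxylate and dicarboxylate metabolism in 25 of 28 (0.40, adjusted p = 0.000163). Without saline replicate 1 these 8 pathways were still called with the preset correlation, with an adjusted p of at most 0.000624. Other immune pathways were split. TNF signaling (77 of 110 genes, adjusted p = 9.86e-05), RIG-I-like receptor signaling (39 of 51, 0.0151) and cytosolic DNA sensing (36 of 49, 0.0172) were called lower, and the intestinal immune network for IgA production higher (19 of 27, 0.00601). Toll-like receptor signaling (47 of 86 lower, 0.222), NF-kappa B signaling (53 of 91 lower, 0.444), cytokine-cytokine receptor interaction (67 of 145 lower, 0.728), antigen processing and presentation (36 of 68 lower, 0.744) and chemokine signaling (75 of 151 lower, 0.843) were not called. The annotated cell cycle pathway was called lower (81 of 125 genes, adjusted p = 0.00967; 0.0218 without saline replicate 1), as was DNA replication (30 of 37, 0.000578; 0.00840), whereas the cell cycle list was not. Conversely, the respiratory chain, cholesterol and fatty acid oxidation lists were called, but related pathways were not. These were oxidative phosphorylation (106 of 170 higher, camera adjusted p = 0.315), steroid biosynthesis (13 of 19 higher, 0.444) and fatty acid degradation (25 of 46 higher, 0.601).

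The pathway tests and the tests of both patterns below were chosen after the results were seen, and the splits of the libraries before. The first pattern is that saline replicate 1 lies nearer to the tacrolimus libraries than to the other saline libraries. A swap between the groups would need a tacrolimus library among the other saline ones, and the smallest mean distance of a tacrolimus library to saline replicates 2 and 3 is 1.00, against at most 0.613 between tacrolimus libraries. Depth is argued against by the totals, since saline replicate 2 has the lowest (38443534 counts) and saline replicate 3 the highest. A wrong label on saline replicate 1 alone cannot be told apart from its label being right: its mean distance to the tacrolimus libraries is 0.602, theirs to each other 0.589, and no marker of identity exists in animals of 1 strain and sex. Graded injury between animals may be the source, as a hypothesis. Saline replicate 1 lies between the tacrolimus and the other saline libraries in 19 of 32 tubular injury and 14 of 35 proximal tubule genes. For the thick ascending limb this holds in 1 of 14 genes, for intercalated cells in 3 of 14 and for podocytes in 0 of 12. It also holds in 9 of 14 neutrophil, 10 of 19 ferroptosis, 13 of 30 ribosomal protein and 10 of 28 respiratory chain genes. The position is thus not particular to injury and proximal tubule genes, and its share over all genes tested was not computed. In the cell cycle list saline replicate 1 lies outside both groups, with 23 of 30 members above all tacrolimus libraries. Its list median, as log2 from the gene means, was 0.71. The tacrolimus libraries had -0.41 to 0.13, and saline replicates 2 and 3 had 0.12 and -0.37. A position between the groups does not describe that list. Whether tacrolimus itself lowered the injury stays open, also because the design text words the ischemia differently for the 2 groups.

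The second pattern is that Ugt1a9 and Gsk3b alone pass the threshold. For Ugt1a9, reads moved between Ugt1a models cannot be told apart from a loss of transcript: the total over these models differed by 17.2 CPM (tacrolimus 977 ± 45.8, saline 960 ± 210, SD, n = 3), and the 68.1 CPM lost lie within that spread. Single libraries of the cluster jump likewise, with 2773 counts of Ugt1a6b in saline replicate 1 against 15 to 72 elsewhere and 158 of Ugt1a1 in saline replicate 2 against 2207 to 3709 (both chosen after their values were seen). For Gsk3b, the 3 overlapping models hold 0 reads in the tacrolimus libraries where 2194 per library are missing, which argues against reads lost to them. Clean jumps that follow no group may be a source: among 8012 genes with a log2 CPM of at least 4, the real groups part 1 gene (Gsk3b) by over 2-fold with a range under 1.3-fold on each side, and other splits of the libraries part up to 2, such as Lrrc47 and Ctdsp2 (named after their values were seen).

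The 6 libraries can be split into 3 and 3 in 10 ways, too few for a share under 0.05. The real split gave 2 genes, also 2 changed at least 2-fold, and 21 lists. The highest of the other splits gave 2 genes, 2 changed at least 2-fold and 23 lists. For each of these counts 2 of the 10 splits, the real one included, gave a value as large. The split with 23 lists puts tacrolimus replicate 1 with saline replicates 2 and 3.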
